A study of Mus musculus with 12 samples.

How the data were processed

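Messenger RNA was profiled by RNA sequencing in mouse hippocampus (strain C57BL6/J). The 12 libraries came from a synapse fraction (6 libraries) or from the whole homogenate (6 libraries), in the arms C and L. Per the file headers, the C columns are named control and the L columns training or learned, except that the day 1 and day 20 synapse columns carry the letters C and T with the day. The day 6 columns of both fractions also carry the word Input, and those of days 1 and 20 do not. Among the synapse libraries, day 6 and this naming cannot be told apart. The synapse fraction has 1 library per arm on each of days 1, 6 and 20, and the homogenate has 3 libraries per arm on day 6, whose columns carry a code shared by 1 library of each arm. Each library was placed in its group by its title. The labels do not say how the synapse fraction was prepared, what was done to the animals, or whether libraries of a group came from separate animals.

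Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into strand-specific (dUTP) libraries with random priming, after fragmentation. Per the submitters' processing notes, cutadapt 1.9.3, HISAT2 2.0.4, HTSeq 0.9.1 and edgeR were used with the mouse build mm10. The annotation release, the strand setting of the counting and any gene filter are not given in the sources used here. The deposited values are raw read counts per gene, which the authors supplied in 4 tables: the synapse pair of each day and the 6 homogenates. Per the file headers, each gene has a biotype, which is protein coding throughout, although some symbols are those of pseudogenes. The tables list 17130 genes for days 1 and 20, 14552 for the day 6 synapse pair and 17458 for the homogenates, and 14360 genes stand in all 4. The day 6 tables list no gene with a count of 0 in all of their libraries, whereas 510 genes of the day 1 table and 600 of the day 20 table are at 0 in both libraries. With the strand setting not given, reads of overlapping antisense genes are not told apart, and genes with near-identical copies are uncertain.

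Total counts were 1.33e+07 (C) and 1.16e+07 (L) for the day 1 synapse pair, 1.53e+07 and 1.17e+07 for day 6, and 1.14e+07 and 1.06e+07 for day 20. The homogenate totals were 1.47e+07, 1.13e+07 and 1.595e+07 for C replicates 1, 2 and 3, and 1.301e+07, 1.19e+07 and 9.10e+06 for L replicates 1, 2 and 3. A count of 0 allows up to 3 counts, which is 0.188 to 0.330 CPM (counts scaled to the library total) over the 12 libraries. Intervals and this limit cover counting error only, since the reads carry no molecular identifiers.

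The homogenates were compared with the quasi-likelihood test of edgeR 4.0.16 (filterByExpr, TMM scaling, robust fit) in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The synapse pairs have 1 library per arm and no test between arms within a day. For these, log2 ratios of TMM-scaled CPM with a prior count of 2 were taken over genes with a mean of at least 10 CPM, and genes past 2-fold were counted. Exact Clopper-Pearson 95% intervals of the share of counts were carried to the log2 ratio. Across days, arm was tested with day as a block. The synapse fraction was compared with the homogenates over the 8 day 6 libraries in a fit with 4 groups, which assumes that the lone synapse libraries vary like the homogenates. Each synapse table was deposited apart from the homogenates, so fraction and table cannot be separated.

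Before the data were examined, 34 gene lists (pathways, synaptic components and markers of cell types or regions), the tests, their alternatives and the rule for naming genes were fixed. In the fits, 32 lists with at least 5 tested members were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the lists. In the synapse pairs, each list's median was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The rule named, in the homogenates, genes past the threshold and, as none passed, the 5 with the smallest p in each direction among genes with a mean of at least 5 CPM and the same direction in all 9 comparisons of an L with a C library. In each synapse pair it named the 8 highest and 8 lowest ratios. Between fractions it named the 10 highest and 10 lowest contrasts past the threshold with at least 10 CPM. It also took up to 4 members of each described list, those with the smallest p in the homogenates or the largest change in the synapse fraction, and always Fos, Egr1, Arc, Npas4, Nr4a1, Bdnf, Camk2a, Dlg4, Mettl3, Ttr, Mbp and Gfap. Some genes that the rule named are not reported here. Predicted genes, pseudogenes and small RNAs were counted but not named by the rule. Lists of liver and pituitary transcripts were written after the data were examined. Gene coordinates are those of GENCODE M21 (GRCm38, the build called mm10), matched by Ensembl gene identifier for 124 of 124 named genes.

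Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, fry, an estimated inter-gene correlation, a block for the replicate number, other expression floors and leaving out each library or day. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, the homogenate test recovered 81% and 100% with 12 false calls among 13475 genes. The test across days recovered 55% and 87% with 6 false calls among 13178 genes, and the comparison of fractions recovered 77% and 97% with 14 false calls among 13918 genes. The simulation of the fractions gave the synapse libraries the spread of the homogenates. Its error rates therefore do not cover the wider spread of the day 6 synapse pair. The simulation across days gave each gene the same level and the same spread on every day, so its rates do not cover that wider spread either. In the list test, a simulated 1.5-fold rise of the immediate early list was recovered with 0 other lists called. The genes were drawn independently of each other there, so that simulation could not test the effect of correlation between genes. Of 100 random lists, 4 lay outside the central 95% of their matched draws. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for the random lists and the plots.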

Results

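Hippocampal mRNA of mice was counted in 12 libraries during learning and memory, in a synapse fraction and in whole homogenates, to compare the arm L with the arm C. The synapse fraction had 1 library of each arm on days 1, 6 and 20, and the day 6 homogenates had 3 libraries of each arm. Library totals ran from 9.10e+06 to 1.595e+07 counts. Nothing in the labels says that the homogenate libraries of an arm came from separate animals, so p-values measure only the spread between these samples, which may be technical.

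In the day 6 homogenates, interferon-induced and inflammatory transcripts were higher in L than in C, with 18 of 18 measured members above 0 and a median log2 difference of 0.67. Chaperone and unfolded protein response transcripts (22 of 24 above 0, median 0.25) and activity-induced immediate early transcripts (28 of 35, median 0.20) were also higher in L. The interferon list kept its call with an estimated correlation between genes, and the chaperone and immediate early lists did not (adjusted p = 0.374 and 0.0723 with an estimated correlation). The interferon call ended with the set test fry (adjusted p = 0.0627) and with a replicate block added to the estimated correlation (camera adjusted p = 0.409). Ribosomal protein transcripts were lower in L by a smaller amount, with 61 of 77 members below 0 and a median of -0.12. That call ended too (adjusted p = 0.675 with an estimated correlation), and without C replicate 3 (median -0.05, adjusted p = 0.175). No single gene passed across all genes in edgeR, whereas DESeq2 called the interferon-list genes Rsad2, Bst2 and Ifit1 and the chaperone Hspa5 (adjusted p from 0.0360 to 0.0435).

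Of 13647 genes tested with edgeR, 0 had an adjusted p under 0.05, 1217 had an unadjusted p under 0.05 (650 higher and 567 lower in L, against 682 from chance) and the smallest adjusted p was 0.467. DESeq2 called 13 genes with 1081 at an unadjusted p under 0.05, and limma-voom called 0 with 1300. The values of all 3 libraries of L lay apart from those of C for 2147 genes, 15.7% of those tested, where chance gives 10%. The 11 genes that DESeq2 called higher in L were the interferon-induced Rsad2, Bst2, Ifit1, Gbp3 and Rnf213, the chaperone Hspa5, and Mtf1, Acer2, Cdh19, Col4a3 and Arhgap31, with Gbp3 and Rnf213 named after their values were seen. The count at an unadjusted p under 0.05 was 383 without C replicate 1 and 761 without C replicate 3, and without C replicate 2 edgeR called 3 genes, the pituitary hormone genes Gh, Prl and Pomc, all lower in L and named after their values were seen.

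The 5 genes with the smallest p among those higher in L did not pass in edgeR, and DESeq2 called all 5 (adjusted p = 0.0360 for each). They were the metal-responsive transcription factor Mtf1 (ENSMUSG00000028890, mm10 chromosome 4, 124802104 to 124849800, plus strand), the alkaline ceramidase Acer2 (ENSMUSG00000038007, chromosome 4, 86874396 to 86934822, plus strand), the cadherin Cdh19, the basement membrane collagen Col4a3 and Arhgap31. Mtf1 was at 46.1 ± 2.48 CPM in C and 64.3 ± 1.23 in L (SD, n = 3), and Acer2 at 5.25 ± 0.758 and 11.3 ± 1.56 (SD, n = 3), a log2 difference of 1.10 (SE 0.21, edgeR adjusted p = 0.467). Col4a3 had a log2 difference of 1.17 (SE 0.22), Cdh19 of 0.67 (SE 0.13) and Arhgap31 of 0.46 (SE 0.09). Each had L above C in 9 of 9 library comparisons, which the naming rule required. Among those lower in L, which passed in neither tool, Pdcd10 had a log2 difference of -0.42 (SE 0.09), Zfp46 of -0.45 (SE 0.10), the tethering-complex subunit Vps11 of -0.38 (SE 0.08), the UFM1-conjugating enzyme Ufc1 of -0.44 (SE 0.10) and Slc25a53 of -0.83 (SE 0.19).

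The interferon and inflammation list had a camera adjusted p = 1.11e-12 over 32 lists, and adjusted p = 0.0384 with an estimated correlation, the only list that kept its call there. With a replicate block as well as an estimated correlation, its camera adjusted p was 0.409. Adjusted over the list alone, 8 of its genes passed in edgeR, all higher in L, against 0 over all genes, where DESeq2 called Rsad2, Bst2 and Ifit1. Bst2, an interferon-induced membrane protein (ENSMUSG00000046718, chromosome 8, 71534255 to 71537456, minus strand), was at 1.16 ± 0.30 CPM in C and 4.16 ± 0.465 in L (SD, n = 3), 3.63-fold apart. Rsad2, which encodes viperin (chromosome 12, 26442746 to 26456452, minus strand), was 4.88-fold higher with 0.906 ± 0.258 against 4.40 ± 2.60 CPM, Ifit1 3.40-fold and Ifi27 1.61-fold. L replicate 1 also held liver transcripts, given further on, and C3, a complement gene of this list that the liver makes, stood at 2.88 ± 1.53 CPM in C and 122 ± 207 in L and was picked out after its values were seen. Without that library the list kept its call at the preset correlation, with a camera adjusted p of 2.26e-09. An estimated correlation was not run without it.

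Of 24 chaperone and unfolded protein response genes, 8 passed in edgeR adjusted over the list alone, all higher in L, and 0 over all genes, where DESeq2 called Hspa5. The endoplasmic reticulum chaperone Hspa5 (chromosome 2, 34771970 to 34777547, plus strand) was at 259 ± 9.18 CPM in C and 375 ± 75.0 in L (SD, n = 3), the transcription factor Xbp1 was 2.01-fold and the inducible chaperone Hspa1a 1.75-fold higher. Hspa5 and Xbp1 were highest in L replicate 1, with Hspa5 at 460 CPM against 344 and 320 in L replicates 2 and 3. Without that library the list had a median of 0.22 and, at the preset correlation, a camera adjusted p of 1.25e-06. The list had a camera adjusted p = 2.83e-10, and adjusted p = 0.374 with an estimated correlation. Of 35 immediate early genes, which neuronal activity induces, 7 passed in edgeR adjusted over the list alone, all higher in L, and 0 over all genes in edgeR or DESeq2. Fos (chromosome 12, 85473890 to 85477273, plus strand) was at 10.8 ± 2.56 CPM in C and 21.1 ± 8.11 in L, Egr2 at 3.61 ± 1.47 and 9.25 ± 2.57, and Arc (chromosome 15, 74669083 to 74672570, minus strand) at 101 ± 12.9 and 160 ± 46.1 (SD, n = 3). Fosb was 1.94-fold and Egr1 1.45-fold higher, whereas Npas4 was at 12.8 ± 2.64 and 13 ± 1.02 CPM, Nr4a1 had a log2 difference of 0.32 (SE 0.29) and Bdnf of 0.07 (SE 0.11). The list had a camera adjusted p = 1.77e-08, and adjusted p = 0.0723 with an estimated correlation.

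Glucocorticoid-induced genes were higher in L in 16 of 17 cases (median 0.37, camera adjusted p = 6.14e-06), with adjusted p = 0.464 with an estimated correlation. Without C replicate 3 their median was 0.24. Among them Zbtb16 was at 121 ± 16.9 CPM in C and 166 ± 29.1 in L, and Tsc22d3 was 1.29-fold higher (SD, n = 3). Choroid plexus and ependymal markers were higher in 17 of 19 cases (median 0.54, camera adjusted p = 2.66e-05), with adjusted p = 0.675 with an estimated correlation. Their mean level stood at 0.97 on the log2 scale above the mean of C in L replicate 3, at 0.26 in L replicate 1 and at -0.03 in L replicate 2, and without L replicate 3 the median was 0.20 (adjusted p = 0.2003). F5 was at 59.8 ± 25.6 and 106 ± 30.5 CPM and Ttr, the thyroxine carrier of the choroid plexus, at 1511 ± 392 and 2140 ± 730 (SD, n = 3). Myelin and oligodendrocyte markers were higher in 18 of 21 cases (median 0.15, camera adjusted p = 0.00871), with adjusted p = 0.754 with an estimated correlation, and Mbp was 1.10-fold higher. Without L replicate 3 their median was -0.01 (adjusted p = 0.954), and without C replicate 3 it was 0.09 (adjusted p = 0.156), against 0.30 without L replicate 1 and 0.29 without C replicate 2.

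The 4 lists lower in L moved by little. Ribosomal protein genes had a camera adjusted p = 6.14e-06, and adjusted p = 0.675 with an estimated correlation, with Rpl35 at 136 ± 1.34 CPM in C and 105 ± 15.9 in L (SD, n = 3) and Rplp0 0.834-fold. Their median was -0.05 without C replicate 3 (adjusted p = 0.175), -0.08 without L replicate 2 and -0.20 without C replicate 2. Nuclear-encoded oxidative phosphorylation genes were lower in 52 of 71 cases (median -0.11, adjusted p = 0.00871), with adjusted p = 0.770 with an estimated correlation, Ndufb6 being 0.764-fold and Uqcrc1 0.851-fold. This call ended without C replicate 3 (0.854), without L replicate 2 (0.570) and without L replicate 3 (0.0657, all adjusted p), with medians of -0.05 without C replicate 3 or L replicate 2 and -0.18 without C replicate 2. GABA receptor subunits were lower in 12 of 14 cases (median -0.09, adjusted p = 0.0172), with adjusted p = 0.5005 with an estimated correlation. The call ended without L replicate 1 (0.107) and without L replicate 3 (0.0984, adjusted p), with medians of -0.06 without L replicate 3 and -0.15 without L replicate 2. Microglia markers were lower in 11 of 16 cases (median -0.12, adjusted p = 0.0364), with adjusted p = 0.426 with an estimated correlation. The chemokine receptor Cx3cr1 was at 41.8 ± 0.887 and 33.3 ± 2.15 CPM and Siglech at 16.1 ± 0.863 and 11.8 ± 0.469 (SD, n = 3). The microglia call ended without C replicate 1 (0.0737), C replicate 3 (0.156), L replicate 2 (0.111) or L replicate 3 (0.0984, adjusted p), with a median of -0.03 without C replicate 3.

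The medians of the other 22 lists ran from -0.33 for meningeal and fibroblast markers to 0.60 for mitochondrially encoded mRNAs, and none of these lists passed. Leaving out 1 library at a time moved the former from -0.46 to -0.13 and the latter from -0.18 to 1.66. The set test fry, which asks whether the genes of a list move one way on balance, called 0 of the 32 lists, with the interferon list at an adjusted p of 0.0627. Camera itself called 16 lists without C replicate 2 and 6 without C replicate 3 or without L replicate 3. Camk2a (log2 difference 0.17, SE 0.11), Dlg4 (0.04, SE 0.07), Gfap (0.05, SE 0.10) and Mettl3 (0.26, SE 0.16) did not pass.

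**Figure D1:**
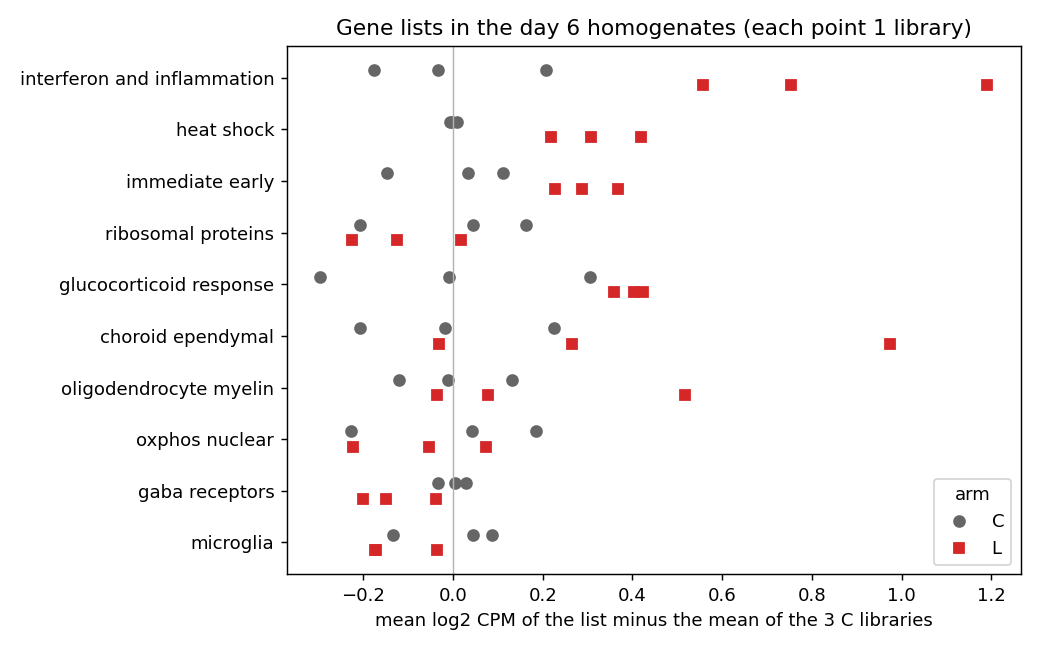
Mean log2 CPM of each of the 10 called gene lists in the 6 day 6 homogenates, relative to the mean of the 3 C libraries (x axis, log2 units; 1 point per library, C as circles and L as squares). All 3 L libraries lie above all 3 C libraries for the interferon, heat shock, immediate early and glucocorticoid lists, whereas L replicate 3 alone carries the choroid plexus list to 0.97.

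**Figure D2:**
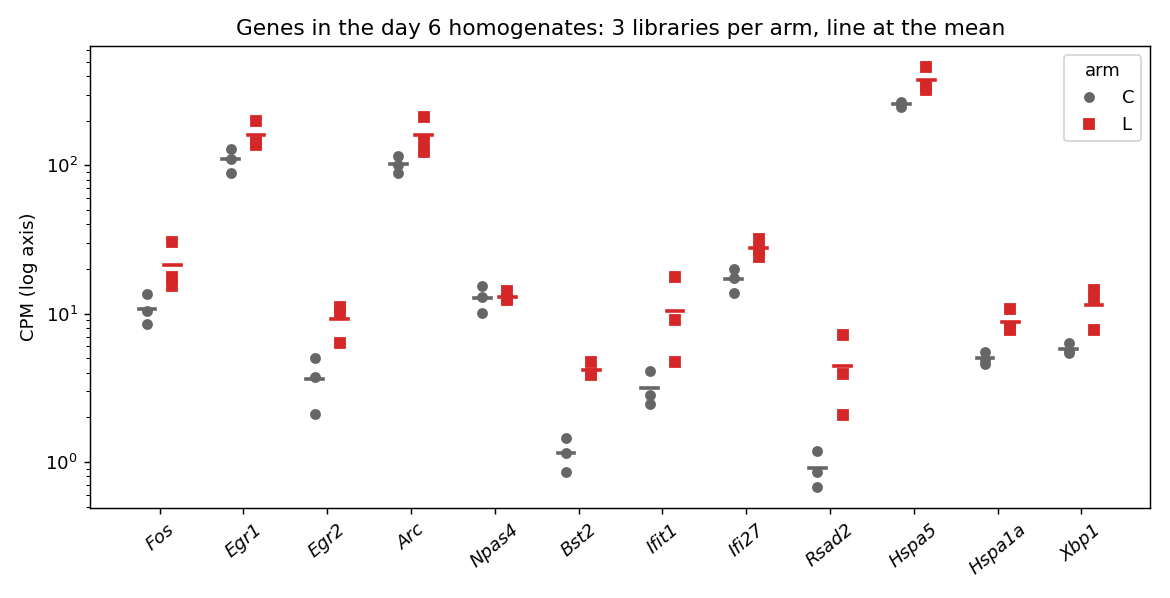
CPM on a log axis of 12 genes of the immediate early, interferon and heat shock lists in the day 6 homogenates, with 3 libraries per arm and a line at each arm's mean. Bst2 lies at 1.16 ± 0.30 CPM in C and 4.16 ± 0.465 in L (SD), and Npas4 overlaps between the arms.

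In the synapse fraction of day 1, immediate early and glucocorticoid-induced transcripts were lower in the L library than in the C library, with medians of -0.29 (24 of 27 genes lower) and -0.34 (15 of 15 lower) on the log2 scale. Transcripts of the postsynaptic density were lower too (30 of 33, median -0.22), and endothelial, meningeal and microglial transcripts were higher, with medians of 0.37, 0.31 and 0.22. There was no replicate of either arm on any day, so the ratios of all 3 synapse pairs describe these libraries and carry no test between arms. Of 31 lists, 15 had a median outside the central 95% of random lists on day 1. Over the 3 days 33 of 93 did, where lists of unrelated genes would give about 4.65. The genes of a list can vary together between libraries, so this excess does not by itself show a difference between the arms.

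Arc, whose mRNA travels to dendrites, had 3030 counts in C and 1317 in L on day 1, a log2 ratio of -1.05 (95% interval -1.15 to -0.96). Npas4 stood at -0.73, Junb at -0.71, Nr4a1 at -0.61 and Egr1 at -0.54, while the interval of Fos (-0.30, from -0.62 to 0.01) held 0. Among glucocorticoid-induced genes, Arrdc2 (-1.19), the cell cycle inhibitor Cdkn1a (-1.19) and the kinase Sgk1 (-0.58) were lower in L. The scaffold genes Shank1 and Shank3 stood at -0.46 and -0.45, and Camk2a at -0.41. Glutamate receptor subunits (median -0.14), dendritic mRNAs (-0.14), ribosomal protein genes (-0.08), cholesterol synthesis genes (-0.12) and CA2 and CA3 markers (-0.17) also lay below their random range. In the other direction, the vessel genes Vwf and Tek stood at 0.85 and 0.80, the microglial Trem2 at 0.40, Islr of the meninges at 0.68 and H2-D1 of the interferon list (median 0.23) at 0.64. Choroid plexus markers (0.17), chaperone genes (0.07) and RNA granule proteins (0.06) had medians above their random range.

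Only 14 of 9311 genes differed by at least 2-fold on day 1, 4 higher and 10 lower in L. The highest ratios were those of Rps27a (1.44), Hist1h4m (1.20), the endothelial thrombomodulin gene Thbd (1.17), Cxx1b (0.95), Gjb2 (0.92), Arhgap29 (0.86), Itih2 (0.86) and Idi1 (0.86). The lowest were those of Prl (-1.76, 401 and 105 counts), Arrdc2, Cdkn1a, Hist1h4n (-1.15), Gh (-1.06), Arl4d (-1.06), Arc and Nrros (-1.05). Rps27a, Hist1h4m and Hist1h4n have near-identical copies in the genome, and their ratios are uncertain.

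On day 6, postsynaptic density transcripts were higher in the L library of the synapse fraction (24 of 32, median 0.17), and so were dendritic mRNAs (14 of 20, median 0.10). Choroid plexus (median -0.33), myelin (-0.31), mitochondrially encoded (-0.26), astrocyte (-0.21), ribosomal protein (-0.19) and nuclear oxidative phosphorylation (-0.14) transcripts were lower. Of the 5 mitochondrially encoded genes 2 were higher, among them mt-Nd4l at 1.49, and at floors of 20 or 5 CPM their median lay inside the random range, as did that of the oxidative phosphorylation genes at 20 CPM. The ratios of the day 6 pair spread far more widely than on the other days, with 511 of 8078 genes past 2-fold (283 higher and 228 lower in L) and a median absolute deviation of 0.40, against 0.17 on day 1 and 0.16 on day 20. In this pair 125 genes had a count of 0 in 1 library and at least 50 in the other, against 1 gene on day 1 and 0 on day 20.

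Dlg1 of the postsynaptic density stood at 1.74 (76 and 210 counts). Among dendritic mRNAs Nrgn stood at 0.31 and Map2 at 0.24, Aqp4 of astrocytes at -0.41 and Aqp1 of the choroid plexus at -1.34. Among the highest ratios of the pair were those of the neurofilament gene Nefh (2.91, 34 and 218 counts), Rgs3 (2.78), Ifit2 (2.54), Sh3rf3 (2.47), Ikzf4 (2.41), Brf1 (2.29) and Baz1b (2.29). Among the lowest were those of the kinase gene Csk (-3.28, 344 and 27 counts), Twistnb (-2.59), Alb (-2.56), Slc25a1 (-2.42), Srp54b (-2.31, with near-identical copies) and Serpina3k (-2.18). Alb and Serpina3k are transcripts of the liver. Of the genes followed on every day, Arc stood at 0.07, Egr1 at -0.68, Nr4a1 at 1.00, Bdnf at -0.08, Camk2a at 0.13, Dlg4 at 0.01 and Mettl3, the catalytic subunit of the m6A writer, at 1.64 from 44 and 115 counts.

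On day 20, immediate early transcripts were higher in the L library of the synapse fraction (21 of 28, median 0.19), and choroid plexus (12 of 12 lower, median -0.30) and meningeal transcripts (12 of 14 lower, median -0.25) were lower. Mitochondrially encoded (0.23), endothelial (0.16), chaperone (0.14) and glucocorticoid-induced transcripts (0.12) had medians above their random range. CA1 markers (-0.15), glutamate receptor subunits (-0.07) and synaptic vesicle genes (30 of 36 lower, median -0.07) lay below it, the glutamate receptors not at a floor of 20 CPM (median -0.05). Differences between the days were not tested.

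Cyr61 stood at 0.99, Fos at 0.75 and Nr4a3 at 0.37 on day 20, whereas the interval of Npas4 (-0.27, from -0.65 to 0.10) held 0. Arc stood at 0.19, Egr1 at 0.25, Camk2a at 0.12, Mbp at 0.17, Ttr at -0.34, Igf2 of the meninges at -0.59 and Slc32a1, the vesicular GABA transporter, at -0.38. The widest ratios were those of the pituitary hormone genes Prl (4.17, 70 and 1199 counts) and Gh (3.48, 460 and 4774 counts), which on day 1 had been lower in L. Of 9307 genes, 2 were higher and 3 lower by at least 2-fold, and after Prl, Gh, Cyr61 and Fos the highest were Mrps31 (0.92), Hist1h2bc (0.82), mt-Nd3 (0.79) and Mvk (0.74). The lowest were Tom1 (-1.11), Acpl2 (-1.07), Synpo2 (-0.97), Ptk7 (-0.93), Prkrip1 (-0.92), Bmp3 (-0.92), Polr2l (-0.90) and Cd74 (-0.87).

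**Figure D3:**
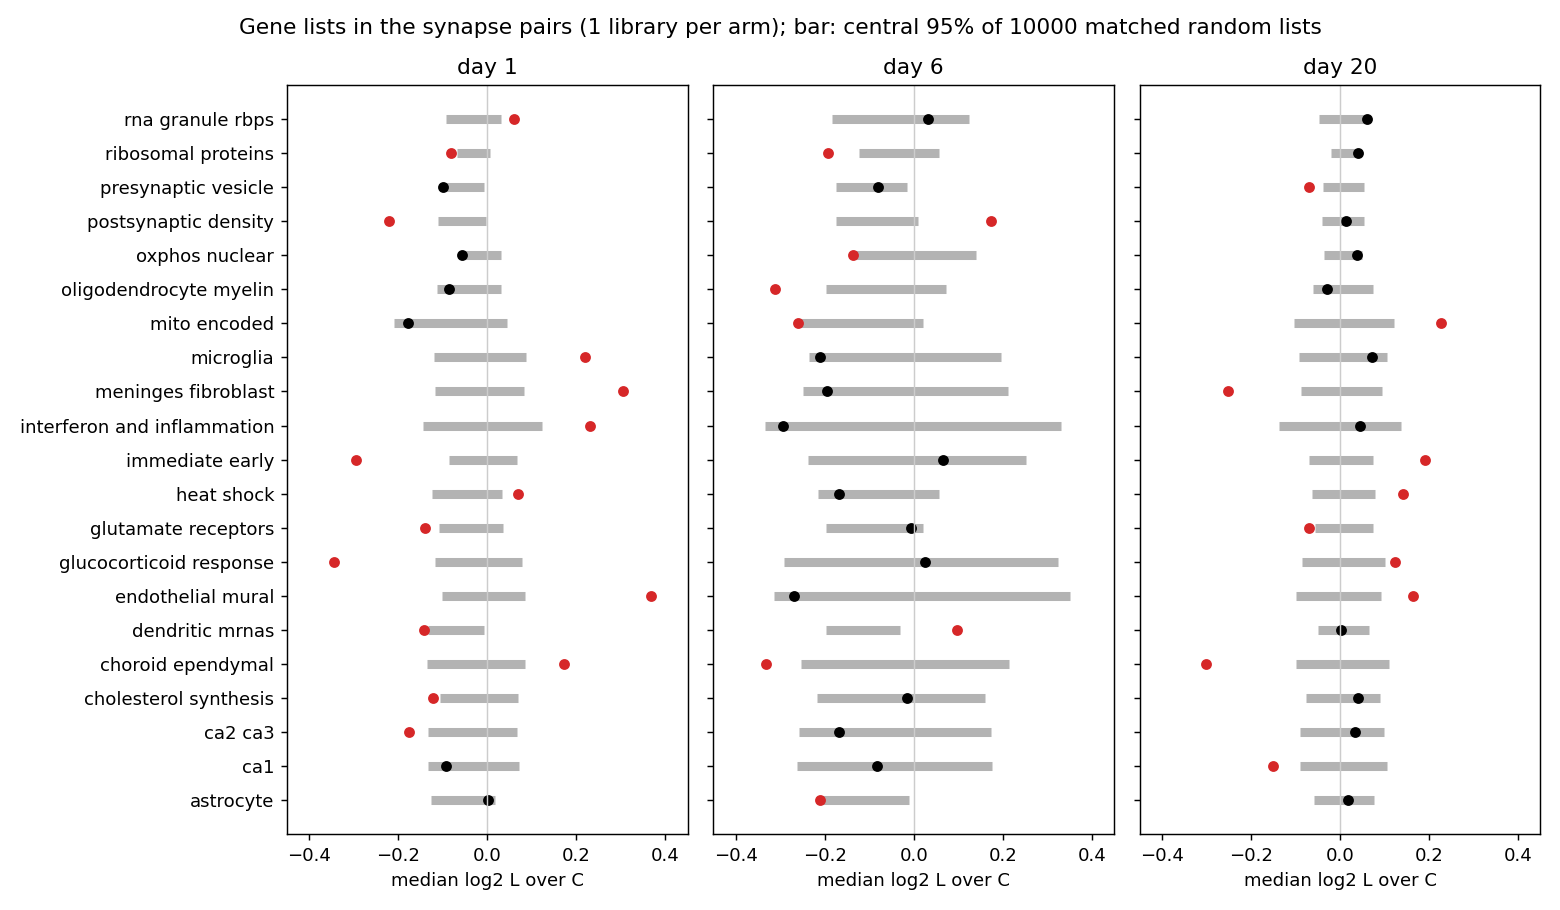
Median log2 ratio of L over C (x axis) of gene lists in the synapse pair of each day, 1 library per arm, with grey bars for the central 95% of 10000 matched random lists and red points for medians outside them. The immediate early list lies at -0.29 on day 1 and 0.19 on day 20, and the random ranges are widest on day 6.

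No gene differed by at least 1.5-fold in the same direction on all 3 days among 7831 genes past the floor on each. Independent days would give 0.0063 such genes higher and 0.0067 lower, so a count of 0 says little. The ratios had the same sign on all days for 29.0% of the 7831 genes, where chance gives 25%, and their Spearman correlations across genes, which are not independent replicates, were 0.01 (days 1 and 6), 0.13 (days 1 and 20) and 0.02 (days 6 and 20). With day as a block, edgeR called 0 of 13363 genes, with 227 at an unadjusted p under 0.05, 49 higher and 178 lower in L. Under library size scaling the lean turned, with 100 higher and 72 lower. Camera called 6 lists lower in L, and all 6 calls ended with an estimated correlation (adjusted p = 0.922 for each). They were synaptic vesicle genes (29 of 36 lower, median -0.10), GABA receptor subunits (13 of 14, -0.11), myelin (19 of 21, -0.16) and oligodendrocyte precursor markers (11 of 12, -0.27), ribosomal protein genes (63 of 75, -0.09) and choroid plexus markers (13 of 17, -0.15). Without day 6 camera called 11 lists, for which an estimated correlation was not run. Of these 6 were lower, the vesicle, GABA receptor, glutamate receptor, postsynaptic density, dendritic and glucocorticoid lists, and 5 were higher, the endothelial (adjusted p = 1.84e-13), chaperone, RNA granule, microglia and interferon lists. Without day 6, 787 genes had an unadjusted p under 0.05 and 1 gene, the predicted Gm21685, was called lower, named after its values were seen. Without day 1 the fit called 7 genes, including mt-Nd4l, Gh, Prl, Alb, Enpp2 and Ttr, also named afterwards, with 618 at an unadjusted p under 0.05, and without day 20 it called 0 with 368.

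The synapse fraction of day 6 was compared with the day 6 homogenates to see which mRNAs it held more or less of. Mitochondrially encoded mRNAs (median log2 difference 3.43), neuropeptide precursors (2.68), microglia markers (2.58), and GABA (2.06) and glutamate receptor subunits (1.77) were higher in the synapse fraction. Of these the first 2 lost their call (adjusted p = 0.192 with an estimated correlation for each) and the other 3 kept it. With the synapse libraries of days 1 and 20 in place of the day 6 pair the medians were smaller, at 2.76, 1.23, 1.78, 0.46 and 0.44 in the same order. Immediate early transcripts (-0.96), actin regulators of spines (-0.55), the m6A machinery (-0.49) and RNA granule proteins (-0.33) were lower. These 4 calls ended with an estimated correlation (adjusted p from 0.156 to 0.238), and the immediate early median was 0.02 against the synapse libraries of days 1 and 20. Postsynaptic density genes, with 12 higher and 12 lower of 33, had a median of 0.04. With the synapse libraries of days 1 and 20 their median was 0.32, with 19 higher and 6 lower. Under library size scaling of the day 6 comparison it was -0.73, so the direction of this list is not settled.

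Of 14137 genes, 9508 passed in edgeR, 4059 higher and 5449 lower in the synapse fraction, and 7568 with arm and fraction as separate terms, which lets the difference between the synapse libraries add to the spread. At 10 to 20 CPM the variance over its Poisson value was 21.6 in the day 6 synapse pair and 1.65 to 6.58 in pairs of homogenates. The 9508 calls and the SEs of the contrasts take the homogenate spread for the synapse libraries and may be too confident. With library size as the only scaling, 11151 passed with 2442 higher and 8709 lower, and the median over all genes moved from -0.22 to -0.99. With the synapse libraries of days 1 and 20 in place of the day 6 pair, a choice made after the data were seen, 8192 passed, 3985 higher and 4207 lower. The contrasts of the 2 sets had a Spearman correlation of 0.52 across 13539 genes, where simulated unchanged synapse libraries against the shared homogenates gave 0.28. With the C homogenates under the day 6 pair and the L homogenates under the other set it was 0.48, and 0.44 the other way round. The covariance was 0.503 against 0.0163 simulated.

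The 10 highest contrasts began with the macrophage elastase Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499, plus strand), which had 662 and 181 counts in the C and L synapse libraries and 4 counts over the 6 homogenates. Next were the lubricin gene Prg4 (4.56, SE 0.25), mt-Nd5 (4.38, SE 0.48), the microglial Ly86 (4.23, SE 0.23), mt-Nd3 (4.15, SE 0.85), the granule protein gene Chgb (3.76, SE 0.11), mt-Nd4 (3.43, SE 0.11), the proteoglycan gene Acan (3.40, SE 0.14), Ly6e (3.39, SE 0.10) and the enkephalin precursor Penk (3.34, SE 0.22). With the synapse libraries of days 1 and 20, Mmp12 had no value and the contrasts of the others were all smaller. They ran from 0.84 for Penk to 3.37 for mt-Nd5, with Chgb at 1.32, Ly6e at 1.39 and Ly86 at 1.77. Mt-Nd4 was at 29167.5 and 23610.5 CPM in the C and L synapse libraries of day 6 and at 2452 ± 444 in the homogenates (SD, n = 6). The 10 lowest each had a count of 0 in 1 of the synapse libraries and 36 to 179 counts in the other. Mecr (0 in C, 36 in L), Wdr90 (40, 0), Tek (0, 49), Atad5 (0, 38), Acta2 (86, 0), Apeh (0, 76), Slx4ip (0, 137), Zfp11 (0, 109), Zfp128 (0, 169) and Chchd6 (179, 0) had homogenate means of 12.4 to 17.5 CPM. With arm and fraction as separate terms, Apeh, Slx4ip, Zfp11, Zfp128 and Chchd6 did not pass (adjusted p from 0.171 to 0.623).

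Of 5 mitochondrially encoded genes 4 were higher, with adjusted p = 0.192 with an estimated correlation. Of 22 neuropeptide precursors 18 were higher and 0 lower, with adjusted p = 0.192 with an estimated correlation, and Trh had 48 and 111 counts. All 16 microglia markers were higher (Itgam 8.70-fold), as were all 14 GABA receptor subunits (Gabbr2 6.31-fold), 22 of 23 glutamate receptor subunits (Grin1 5.03-fold, Grm5 4.93-fold) and all 18 astrocyte markers (Ndrg2 4.28-fold, S100b 4.17-fold, Gfap 3.83-fold). With the synapse libraries of days 1 and 20, 9 GABA receptor subunits were higher and 1 lower, and 16 glutamate receptor subunits higher and 2 lower. These 4 lists kept their calls with an estimated correlation, with adjusted p from 0.0162 to 0.0278. Higher as lists only at the preset correlation were meningeal genes (10 of 16, Apod 6.09-fold), with adjusted p = 0.424 with an estimated correlation, myelin genes (17 of 21, Trf 4.62-fold and Mbp 1.88-fold), with 0.471, precursor markers (7 of 12, Gpr17 5.69-fold, while Bmp4 had 67 and 0 counts), with 0.226, and CA1 markers (5 of 11, Nov 6.95-fold), with 0.212. The camera direction was also upward for cholesterol synthesis (13 of 19, Sc5d 4.30-fold), ribosomal protein (60 of 77, Rpl37a 2.74-fold), interneuron (10 of 19, Reln 9.56-fold) and synaptic vesicle genes (17 higher and 14 lower of 36, Syp 7.75-fold), whose medians of 0.73, 0.70, 0.50 and 0.10 turned to -0.04, -0.07, -0.27 and -0.67 under library size scaling. Their adjusted p with an estimated correlation was 0.193, 0.556, 0.465 and 0.193.

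Of 35 immediate early genes 25 were lower and 4 higher. Fos had 1 count in the C and 40 in the L synapse library, Npas4 14 and 48, Egr2 0 and 15, Egr4 15 and 0, against homogenate means of 13.95 ± 6.79, 11.3 ± 1.58, 5.62 ± 3.14 and 4.22 ± 1.78 CPM (SD, n = 6). Egr1 was lower (-0.78, SE 0.19), but did not pass with arm and fraction as separate terms (edgeR adjusted p = 0.0585). Nr4a1 was lower too (-1.01, SE 0.33), Arc did not pass (-0.09, SE 0.20) and Bdnf was 3.66-fold higher. Against the libraries of days 1 and 20 the median of this list was 0.02, and Arc (0.57), Nr4a1 (0.65) and Egr4 (1.16) had positive contrasts. There Bdnf stood at 0.08 and did not pass (edgeR adjusted p = 0.380). Spine actin regulators were lower in 22 of 30 cases (Arpc5 5 and 69 counts, Wasl 0.459-fold), the m6A machinery in 12 of 20 (Rbm15 35 and 210 counts, Mettl3 44 and 115) and RNA granule proteins in 16 of 27 (Cpeb1 0.301-fold, Tia1 0.338-fold). With an estimated correlation the adjusted p was 0.192 for immediate early, 0.156 for spine actin, 0.192 for m6A machinery and 0.238 for RNA granule genes. Camk2a was 1.58-fold and Ttr 2.71-fold higher, and Dlg4 did not pass (0.07, SE 0.07), with Camk2a at -0.11 and Dlg4 at -0.70 under library size scaling. The 14 lists left had an adjusted p above 0.05.

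**Figure D4:**
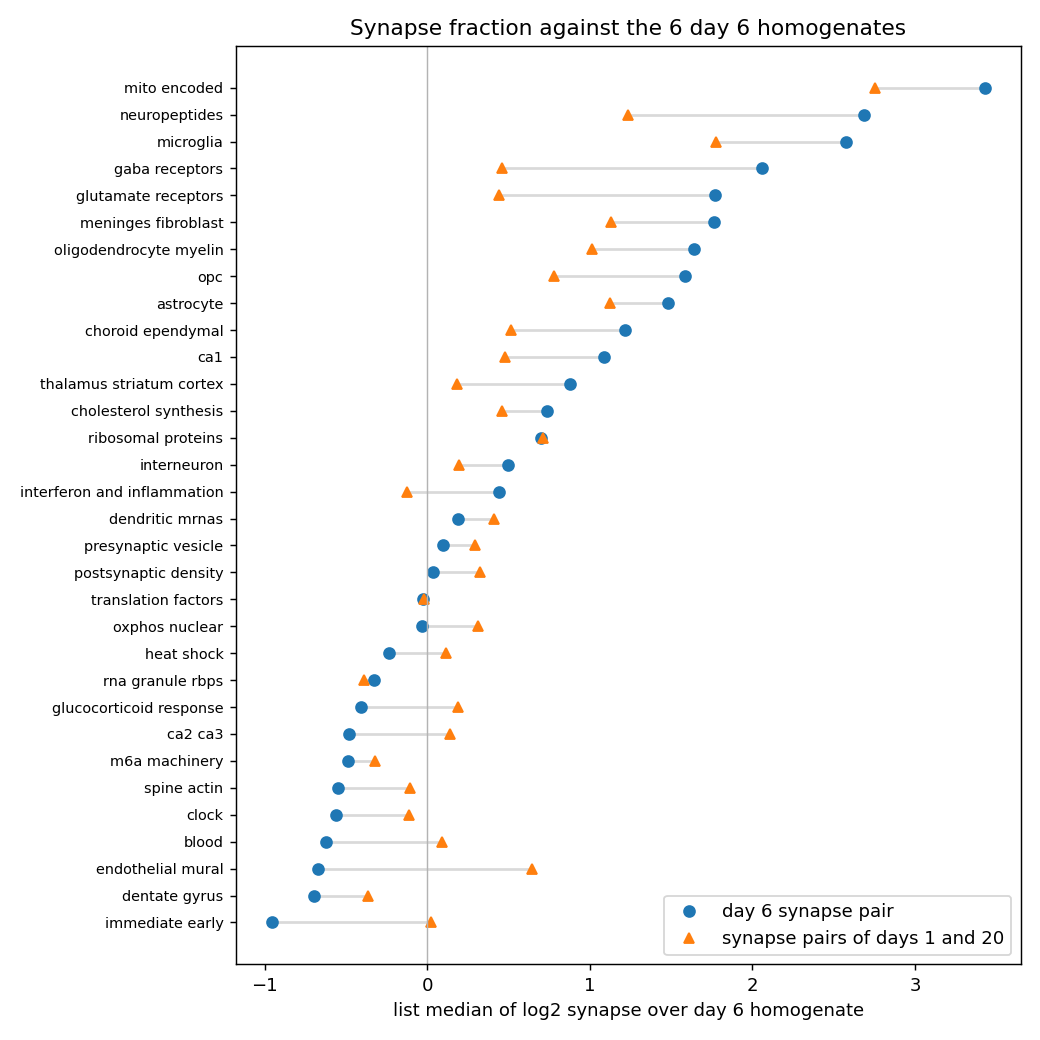
Median log2 difference between the synapse fraction and the 6 day 6 homogenates (x axis) for 32 gene lists, with circles for the day 6 synapse pair and triangles for the 4 synapse libraries of days 1 and 20. The mitochondrially encoded list lies at 3.43 and 2.76, and the immediate early list at -0.96 and 0.02.

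Ratios of L over C were compared across genes between the day 6 synapse pair and the day 6 homogenates, which share no library. Immediate early, interferon and choroid plexus transcripts, higher in L in the homogenates, had medians of 0.07, -0.29 and -0.33 in the synapse pair, of which the first 2 lay inside their random range. These medians covered 17, 9 and 12 genes past 10 CPM, against 35, 18 and 19 genes tested in the homogenates. They do not show how the members under the floor moved. At a floor of 20 CPM the interferon median was -0.05 over 5 genes. In the homogenates the immediate early and choroid plexus calls had ended (adjusted p = 0.0723 and 0.675 with an estimated correlation), the latter also without L replicate 3 (adjusted p = 0.2003). Over 7760 genes the Spearman correlation was 0.05, with the same sign for 52.3%, and genes are not independent replicates. The value was 0.02 without L replicate 2 and 0.01 without C replicate 3 of the homogenates. The day 1 synapse pair had a correlation of -0.08 and the day 20 pair of 0.00 with the same homogenates.

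Transcripts of other organs stood out in some libraries. Alb, the serum albumin gene of the liver (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602, plus strand), had 21975 counts in homogenate L replicate 1, 1575 in the C and 215 in the L synapse library of day 6, and 0 or 1 in each of the other 9. Gh (chromosome 11, 106300271 to 106301865, minus strand) had 254, 15 and 474 counts in C replicates 1, 2 and 3 of the homogenates and 1, 0 and 4 in L. It was called lower in L by DESeq2 (adjusted p = 0.0360), by edgeR without C replicate 2 (adjusted p = 0.00175) and by edgeR with a replicate block (adjusted p = 6.23e-05). The main edgeR test did not call it (adjusted p = 0.467). In the synapse pairs Gh had 1461 and 628 counts in C and L on day 1, 82 and 114 on day 6, and 460 and 4774 on day 20. Without homogenate L replicate 1, edgeR called 0 genes with 1175 at an unadjusted p under 0.05, and camera at the preset correlation called 9 gene lists.

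**Figure D5:**
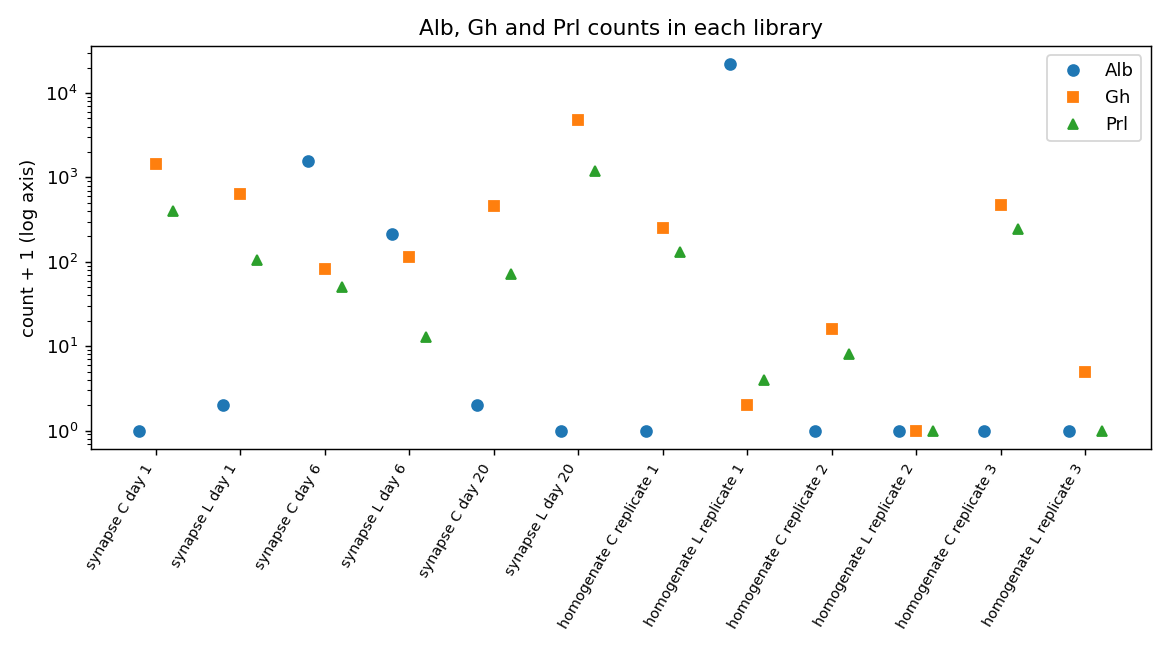
Counts plus 1 on a log axis of the liver gene Alb and the pituitary genes Gh and Prl in each of the 12 libraries. Alb reaches 21975 counts in homogenate L replicate 1, and Gh runs from 0 counts in homogenate L replicate 2 to 4774 in the L synapse library of day 20.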

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

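The tests of few RNA molecules and of sequencing depth were chosen after the spread of the day 6 synapse pair was seen. The difference between the arms differed between the fractions at day 6 for 2569 of 14137 genes by an edgeR interaction test, with a ratio of L over C that was higher in the synapse fraction for 1507 and lower for 1062. With 1 synapse library per arm, this test takes the spread of the homogenates for that of the synapse libraries. The values break that assumption: at 10 to 20 CPM the variance over its Poisson value was 21.6 in the day 6 synapse pair and 1.65 to 6.58 in pairs of homogenates, so the count does not show that the arms acted differently in the fractions.

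Several gene lists lay outside their random range on opposite sides on different days in the synapse pairs, and the differences between days were not tested. Immediate early genes had a median log2 ratio of -0.29 on day 1 and 0.19 on day 20, and glucocorticoid-induced genes -0.34 and 0.12. Postsynaptic density genes stood at -0.22 on day 1 and 0.17 on day 6, and dendritic mRNAs at -0.14 and 0.10. Mitochondrially encoded mRNAs stood at -0.26 on day 6, with 2 of 5 genes higher and the median inside the random range at floors of 20 or 5 CPM, and at 0.23 on day 20. Choroid plexus markers stood at 0.17 on day 1, -0.33 on day 6 and -0.30 on day 20, and meningeal markers at 0.31 on day 1 and -0.25 on day 20. With 1 library per arm and day, differences between samples and differences between arms are confounded in each of these medians.

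The ratios of the day 6 synapse pair spread over a median absolute deviation of 0.40, against 0.17 and 0.16 on days 1 and 20. Lower depth is argued against, since the smaller of the ratios of day 6 to day 1 total counts was 1.01. A candidate explanation is that few RNA molecules lay behind the reads: the variance over its Poisson value above 300 CPM was 1.63 times that at 10 to 20 CPM, where days 1 and 20 gave 7.63 and 6.00, and at 10 to 20 CPM it was 21.6, against 2.69 and 2.56. A low ratio is not specific to this pair, since C and L replicates 2 of the homogenates gave 1.26, though with 4.42 at 10 to 20 CPM. A difference between the arms stays open, because 254 of 504 genes past 2-fold, 50.4% (exact interval 45.9 to 54.8%), moved the same way in the homogenates, which does not exclude a change in the synapse fraction alone.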

How the results depend on the processing

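The day 1 and day 20 synapse libraries in place of the day 6 pair, the synapse lists of days 1 and 20 alone, the replicate block with an estimated correlation, and arm and fraction as separate terms were chosen after the data were seen. Over all alternatives, 50 values of the comparisons stayed within the set bounds, 9 were stronger, 8 weaker, 4 moved and 0 reversed. Of the values of single genes and lists, 2445 kept their direction and side of the threshold or moved by less than their spread, 11 were stronger, 60 weaker, 23 moved and 23 reversed. Where no cause is named, the cause was not tested.

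In the homogenates edgeR called 0 genes, against 1 (Gh) with a replicate block and 13 with DESeq2, and 0 to 3 without each library, the 3 being without C replicate 2. The deviations of C and L libraries with the same number had correlations of 0.01, 0.25 and 0.18, and libraries 2 and 3 of each arm correlated best with their own number, but libraries 1 with number 3, so the shared codes were not taken as pairs. The 10 called lists became 1 with an estimated correlation, 0 with fry, 12 with a replicate block, which kept all 10, 0 with a replicate block and an estimated correlation, and 6 to 16 without each library. Without each library the median of the myelin list ran from -0.0052 to 0.30, Mbp from -0.13 to 0.30, Gfap from -0.071 to 0.12, Nr4a1 from -0.041 to 0.52 and Npas4 from -0.13 to 0.16, with Npas4 at -0.053 without L replicate 3 and -0.0071 in limma-voom. None of these 4 genes had passed the test.

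The number of genes past 2-fold in the synapse pairs followed the expression floor, which sets how many genes are counted. At floors of 20 and 5 CPM it was 5 and 32 for synapse L versus C, day 1, and 175 and 1132 for synapse L versus C, day 6. For synapse L versus C, day 20, it was 2 and 19. Across days, leaving out each day gave 0 to 7 called genes, 7 without day 1 and 1 without day 6. The number of lists outside the random range, 33, ran from 33 to 38 with other floors and bins, and was 25 on days 1 and 20 alone.

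Between fractions the count of called genes ran from 6808 (L libraries alone) to 11151 (library size only). With C libraries alone Chchd6 stood at 0.48, Arc at 0.23 and Bmp4 at 1.40, and with L libraries alone Zfp128 at 0.71, since Chchd6, Bmp4 and Zfp128 have a count of 0 in the synapse library left out. Against the synapse libraries of days 1 and 20 the contrasts were 0.23 for Chchd6, 0.19 for Tek, 0.084 for Wdr90, 0.57 for Arc, 0.064 for Egr1, 0.65 for Nr4a1, 0.11 for Fos, 0.55 for Bmp4 and 1.16 for Egr4. Library size scaling gave -0.11 for Camk2a and -0.70 for Dlg4, and Arc ran from -0.17 to 0.038 without each homogenate library. With arm and fraction as separate terms 7568 genes passed. Chchd6, Zfp128, Zfp11, Slx4ip and Apeh (adjusted p from 0.171 to 0.623) and Egr1 (adjusted p = 0.0585) no longer did.

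The correlation of the day 6 ratios was 0.092 at 20 CPM, 0.0058 as Pearson's r and 0.013 to 0.075 without each homogenate library, with 0.025 without L replicate 2. Pseudocounts for normalized values were not run, since the values are counts. DESeq2 gave no adjusted p for 274 genes. Depth limits the genes near the floor, where 3 counts stand for 0.188 to 0.330 CPM.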

Other observations

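The tests of liver RNA, of a response of liver genes to the L arm, of a fall of Gh with the L arm, of the 8 restricted pituitary genes, of more glial cells and of noise behind the class difference were chosen after the results were seen. The 6 homogenates can be split into groups of 3 in 10 ways, so the share of splits with a result as large is never under 0.1. For genes at an unadjusted p under 0.05, 4 of 10 splits gave at least the 1217 of the real split, and the highest of the others gave 1652. That split, with C replicates 1 and 3 and L replicate 3 on the one side, called 22 genes where the real split called 0, which points to a structure of the samples other than the arms. The 3 other splits that reached 1217 each kept the C and L library together for 2 of the shared column codes. Of the splits that did so, 3 more gave only 253, 91 and 182 genes. The 3 splits that, like the real one, divide the C and L library of every code gave 295, 656 and 48 genes. These 4 splits are too few for a share under 0.05. For gene lists, 3 of 10 splits gave at least the real 10, and the splits other than the real one gave 4 to 12. The 3 that divide every code gave 8, 11 and 5 lists. In the synapse comparison across days, 3 of 10 splits gave at least the real 227 genes, and the highest other gave 7117. In the splits with 7117 genes, 6033 passed the adjusted threshold. There both libraries of day 1 lay on one side and both of day 20 on the other, so the day 6 pair alone carried the contrast. The 3 other splits that part the arms within every day gave 105, 153 and 155 genes, and these 4 splits are too few for a share under 0.05.

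In homogenate L replicate 1, 40 of 41 liver genes had at least 10 counts, with Alb at 21975 and Apob at 8850, against 7 of 41 in each other homogenate, and the day 6 synapse libraries had 31 (C) and 22 (L) of 36, against 7 or 8 of 29 on days 1 and 20. The summed CPM of these genes apart from Ttr in homogenate L replicate 1 was 42.8 times that of the next homogenate, and L replicates 2 and 3 reached at most 0.0197 of it, which argues against a response to the L arm and is consistent with liver RNA in that library. A fall of Gh with the L arm in every set is argued against by its log2 ratio of 3.48 in the day 20 synapse pair. Pituitary RNA in differing amounts stays open: Gh and the other pituitary genes had a Spearman rho of 0.566 over the 12 libraries (permutation p = 0.0606, two-sided), a Pearson r of 0.136 (permutation p = 0.647; 0.144 without the 2 farthest libraries), with 3 of the 12 genes at 10 or more counts even in L replicates 1 and 3, and rho of 0.43 in the homogenates and -0.49 in the synapse fraction, a comparison within fractions that was required only after the first rho was seen. The summed level of those other genes was mostly Chga and Pcsk1, at 345 CPM in the C synapse library of day 6. In homogenate L replicate 2, where Gh had 0 counts, these genes still stood at 56.9 CPM, so that rho could not decide. With 8 genes that brain cells express little, rho was 0.636 (permutation p = 0.0298), r 0.339 (permutation p = 0.148; 0.451 without the 2 farthest), and rho 0.60 and 0.83 within the fractions, so pituitary RNA may be in the libraries, but r did not pass and these genes were picked after the first test. Of the 8, only Pomc and Lhb are listed for the day 6 synapse pair.

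In the day 6 comparison of fractions, 4139 genes of membrane or extracellular proteins had a median contrast 1.71 above that of 9272 other genes. More glial cells as the whole cause are argued against by the glutamate and GABA receptor genes, which neurons express, with a median of 1.898 and 36 of 37 higher (medians of 0.44 and 0.46 with the synapse libraries of days 1 and 20). Noise of the day 6 synapse libraries as the source of the class difference is argued against by the smaller of the gaps with C and L libraries alone, 1.62, while the correlation of these contrasts across genes, 0.54, lay between the bounds set for noise and for none. A candidate explanation is mRNA bound to membranes of the endoplasmic reticulum in the fraction, since the gap was also 0.67 among astrocyte, microglia and myelin markers. That gap rests on 40 membrane or extracellular markers (median 1.93) and 14 other markers (median 1.25). The 14 others lay far above the median of -0.46 of the 9272 other genes, which membrane binding leaves unexplained. More glial cells as a part of the cause therefore stay open. With the synapse libraries of days 1 and 20 the gaps were smaller, 0.65 over all genes and 0.35 among the glial markers.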
